A study of Mus musculus with 8 samples.

How the data were processed

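RNA was measured in 8 libraries of parietal bone, the flat bone of the skull roof, from C57BL/6J mouse pups: 4 from pups given an isotype control antibody and 4 from pups given an antibody that blocks CSF1R. CSF1R is the receptor for CSF1 and IL-34 on monocytes, macrophages and osteoclasts. Per the labels, doses were given across the skull on postnatal days 2, 4 and 6, and the bone was taken after perfusion on postnatal day 9. Per the labels' protocols, 1 µg of RNA entered a stranded poly(A) library kit (TruSeq Stranded mRNA), and paired reads of 101 bp were made on a NovaSeq, to 6 Gb for each sample. Libraries are named by their group and the number in their title (isotype 2 to 5, anti-CSF1R 7 to 10). The numbers are not shared between the groups, so no pairing was used. The labels do not say that each library is a separate pup, so p-values measure the spread between these libraries.

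The values used are raw counts per gene symbol, as deposited by the authors in a single table of 27133 genes, 5009 of which had no count in any library. STAR 2.7.10b and featureCounts 1.6.3 are named in the submitters' processing notes, with the genome builds GRCm38 and GRCm39 and no role for either. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so overlapping and antisense genes and close paralogs (such as the C1q, Ms4a and haemoglobin genes) carry that uncertainty. Gene names follow the NCBI RefSeq style. Of 1331 entries whose names begin with LOC1185, 0 were in the RefSeq gene table of GRCm38.p6, so the build of the counts could not be settled and no coordinates are printed. Total counts ran from 57.5 M to 69.1 M per library. Between 82.8% and 84.7% of the counts from 1 to 10 were even numbers, as arises when both mates of a pair are counted. The number of fragments is therefore about a factor of 2 lower and counting noise is larger than the totals imply. A count of 3, taken as the detection floor, equals 0.0434 to 0.0522 CPM and covers counting error only. In each group, pairs of libraries differed by a squared difference of at least 8.61 times that of counting noise (median over 8632 genes with a mean count of at least 1000). That noise was taken for independent counts, and with both mates counted the ratio is about a factor of 2 lower. It stayed above that of counting noise, so no library was a copy of another.

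The comparison of anti-CSF1R with isotype used edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr (17028 genes), TMM factors, robust dispersions, the quasi-likelihood F-test and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are log2 values, anti-CSF1R minus isotype, with their standard error, and expression is given as CPM with TMM library sizes, mean ± SD over 4 libraries. Of the gene lists fixed before the data were examined, 38 in all, 37 were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided and adjusted over the 37 lists. Sex-linked genes served only as a check. Each list was also tested with an estimated correlation and with fry, and its members were counted past the threshold over all genes and adjusted over the list alone. A list score is the mean log2 CPM (prior count 2) of the members in a library. Differences between list scores were tested with an exact two-sided permutation test over 70 assignments, adjusted over 3 such differences. The smallest p it can give is 0.0286.

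The rule for named genes was fixed before the data were examined. It takes Csf1r, Csf1 and Il34. It then takes the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1, no overlap between the groups and a symbol of their own. Last, it takes, per list, up to 4 members with the smallest p, or up to 2 with the highest CPM where no member passed. The rule named 97 genes, of which 74 are printed; 2 genes are not reported here, though they stayed in all tests of genes and lists. Where a list that is not about osteoclasts, macrophages, monocytes, osteoblasts or osteocytes was not called and had no member past the threshold, only its member with the highest CPM is given.

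Alternatives planned before the data were examined were RLE factors, library size alone, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 4 libraries, and the skeletal muscle list score as a covariate. Also planned were leaving out each library, a prior count of 0.5 and medians in place of means for list scores. Isotype libraries 3 and 4 were found to stand apart, and 3 alternatives were added after that: isotype 2 and 5 only against the 4 anti-CSF1R libraries, an offset per library for GC content and transcript length, and counts halved. The offset came from natural splines (5 degrees of freedom each) of a gene's deviation from its mean on GC content and log2 length of the longest GENCODE M21 transcript of that symbol, which 94.0% of the tested genes had. It can also remove true changes that run with GC content or length. The genes called with the offset were also counted without each library in turn.

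The code was tested on simulated data: 5 draws of counts with the means, library sizes and dispersions of these libraries and 200 changed genes each, for anti-CSF1R against isotype, with 16853 genes tested on average. The main comparison recovered 88.1% of the genes changed 4-fold, 21.7% of those changed 2-fold and 0.601% of those changed 1.5-fold, and 4.31% of its calls were false. With the dispersions of the other 6 libraries and a GC trend put on isotype 3 and 4 (16869 genes tested on average), it recovered 62.5% of 2-fold changes. The GC and length offset recovered 83.7%, with 7.32% of its calls false. The simulated trend was linear in GC content, the same in both libraries and without a length term. The real trends of isotype 3 and 4 were not, so 7.32% need not hold for the real data. Isotype 2 and 5 only (16977 genes tested on average) recovered 76.1% of 2-fold changes, with 9.50% of its calls false, above the 5% aimed for. In a draw with the osteoclast list lowered 2-fold, camera called that list and 0 of the 36 others. The simulated genes were drawn independently of each other, so this draw cannot show false list calls that arise from correlated genes.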

Results

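Poly(A) RNA of the parietal bone was compared between pups given a CSF1R-blocking antibody on postnatal days 2, 4 and 6 and pups given an isotype control, both collected on postnatal day 9. The comparison asks how the skull bone transcriptome differs after a treatment meant to deplete myeloid cells. There were 4 libraries per group. Total counts were 63.5 M, 62.3 M, 66.5 M and 67.2 M in isotype libraries 2, 3, 4 and 5. They were 67.8 M, 69.1 M, 66.4 M and 57.5 M in anti-CSF1R libraries 7, 8, 9 and 10. Collagen type I (Col1a1 and Col1a2 together) took 15.8% to 26.8% of all counts. The 4 Y-linked genes examined stood at or below 0.139 CPM in every library. Xist stood at 551, 204, 150 and 710 CPM in isotype 2 to 5 and at 608, 803, 836 and 839 CPM in anti-CSF1R 7 to 10, lowest in isotype 3 and 4. High Xist with Y-linked genes this low is the pattern of female pups, and every library had it.

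Isotype libraries 3 and 4 stood apart from the other 6. Their Spearman correlation with those 6, across genes, was 0.802 to 0.863, against 0.976 to 0.995 among the 6 and 0.979 between the pair. Transcripts rich in GC were over-represented in both, with a Spearman correlation across genes between GC content and the deviation from the median library of 0.696 and 0.682 (-0.440 to -0.0045 in the others). Mitochondrially encoded transcripts took 0.864% and 0.868% of their counts against 2.05% to 2.82% elsewhere. Because both belong to the isotype group, the comparison was also made without them (isotype 2 and 5 only) and with a GC and length offset.

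**Figure D1:**
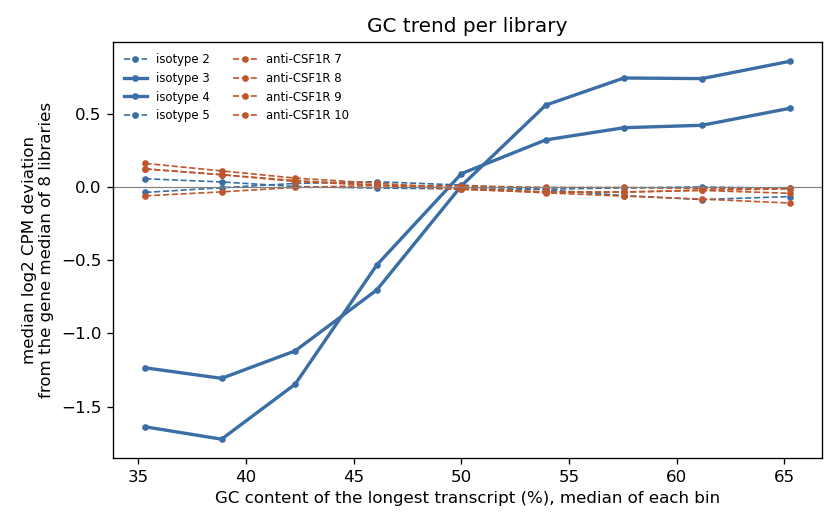
Median log2 CPM deviation of genes from their median over the 8 libraries (y axis), by GC content of the longest transcript in percent (x axis), one line per library; blue is isotype, orange anti-CSF1R, and solid lines are isotype 3 and 4. These 2 libraries rise with GC content, while the other 6 lie close to 0 over the whole range.

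Blocking CSF1R lowered a set of osteoclast and macrophage transcripts in the parietal bone. Of 17028 genes tested, 144 differed between the groups, 140 lower and 4 higher with anti-CSF1R (edgeR, adjusted p under 0.05). The target gene itself, Csf1r, fell 6.34-fold, from 361 ± 152 CPM (SD, n = 4) to between 39.4 and 64.4 CPM in the 4 anti-CSF1R libraries, a log2 fold change of -2.66 ± 0.32 (SE) and an edgeR adjusted p of 0.0156. The antibody acts on the receptor protein, so the RNA does not measure the blockade itself. Of the receptor's ligands, Il34 stood at 15.9 ± 3.95 CPM with isotype and 12.9 ± 0.780 CPM with anti-CSF1R (log2 fold change -0.30 ± 0.19, edgeR adjusted p = 0.320). Csf1 stood at 151 ± 18.9 and 239 ± 17.9 CPM, higher in 4 of 4 anti-CSF1R libraries than in any isotype library. It did not pass over all genes (log2 fold change 0.66 ± 0.15, edgeR adjusted p = 0.0826). It passed with isotype 2 and 5 only (0.78, edgeR adjusted p = 0.00108) and with the GC and length offset (0.85, edgeR adjusted p = 0.00276), in a range of 0.00108 to 0.282 over 18 alternatives. The number of genes called rested on the libraries used. It was 536 with isotype 2 and 5 only and 450 with the offset, each sharing 133 of the 144. The edgeR test called 0, 0, 4 and 14 genes without anti-CSF1R 7, 8, 9 or 10 (1903 and 1597 genes had an unadjusted p under 0.05 without 7 and without 8). It called 35 without isotype 4, 260 without isotype 2 and 234 without isotype 5. With the muscle score as a covariate edgeR called 0 genes (930 with an unadjusted p under 0.05), and DESeq2 called 734 on all libraries. Csf1r stood at 549 and 421 CPM in isotype 3 and 4 and at 238 CPM in isotype 2 and 5. Its log2 fold change was -2.06 with isotype 2 and 5 only. The call was lost without any 1 of the anti-CSF1R libraries (edgeR adjusted p = 0.0564 to 0.0812) and with the muscle covariate (0.109), in a range of 1.73e-13 to 0.109 over 18 alternatives. Of 21 printed genes past the threshold, the fits without 1 library gave 168 values, 92 of them short of it and 0 of them reversed. The values of these 21 genes did not overlap between the groups, so a reversal without 1 library was hardly possible.

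Of the 10 steepest falls that met the rule for named genes, 6 were of genes on the macrophage list: Csf1r, C1qa, C1qb, C1qc, Ms4a7 and Cbr2. Fcrls, a scavenger receptor gene of microglia and related macrophages, fell from 13.9 ± 4.42 to 0.716 ± 0.315 CPM, 19.3-fold lower (edgeR adjusted p = 0.00584). The 3 chains of complement C1q fell with it, C1qc 9.89-fold, C1qa 8.41-fold and C1qb 7.53-fold (edgeR adjusted p = 0.0156, 0.0213 and 0.0159). Qprt, an enzyme of NAD synthesis, fell 9.70-fold, Cd4, the helper T cell co-receptor that some myeloid cells also carry, 8.78-fold, and Serpind1, the gene of heparin cofactor II, 8.74-fold. Ms4a7 and Cbr2 fell 6.88-fold and 6.58-fold. These 5 had edgeR adjusted p-values of 0.0198, 0.0156, 0.0156, 0.00978 and 0.0156. With isotype 2 and 5 only the log2 fold changes of C1qa, C1qb, Qprt and Cbr2 were -2.41, -2.28, -2.45 and -2.01, against -3.07, -2.91, -3.28 and -2.72 on all libraries. With the offset that of C1qa was -2.48 and that of Ms4a7 -3.37, against -2.78 on all libraries. Among genes that rose, 2 met the rule for named genes. Fabp4, a fatty acid binding protein of adipocytes and capillary endothelium, rose from 58.4 ± 4.46 to 103 ± 3.49 CPM (edgeR adjusted p = 0.0267). Veph1 rose from 25.1 ± 2.12 to 41.4 ± 2.34 CPM (edgeR adjusted p = 0.0436). Both lost the call with the GC and length offset, which left log2 fold changes of 0.24 and 0.08 (edgeR adjusted p = 0.472 and 0.847). Both kept it with isotype 2 and 5 only, at 0.73 and 0.75 (edgeR adjusted p = 4.65e-04 and 0.00157). Over 18 alternatives the adjusted p ranged from 3.12e-10 to 0.472 in Fabp4 and from 7.07e-05 to 0.847 in Veph1 with edgeR, DESeq2 or limma. The other 2, chosen after their values were seen because they complete the count, were Klhdc7a (0.327 to 1.48 CPM) and Clec4e, the gene of the innate lectin receptor Mincle (0.160 to 1.08 CPM). Clec4e lost the call with the offset (log2 fold change 2.14 against 2.73, edgeR adjusted p = 0.0649), and Klhdc7a kept it.

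**Figure D2:**
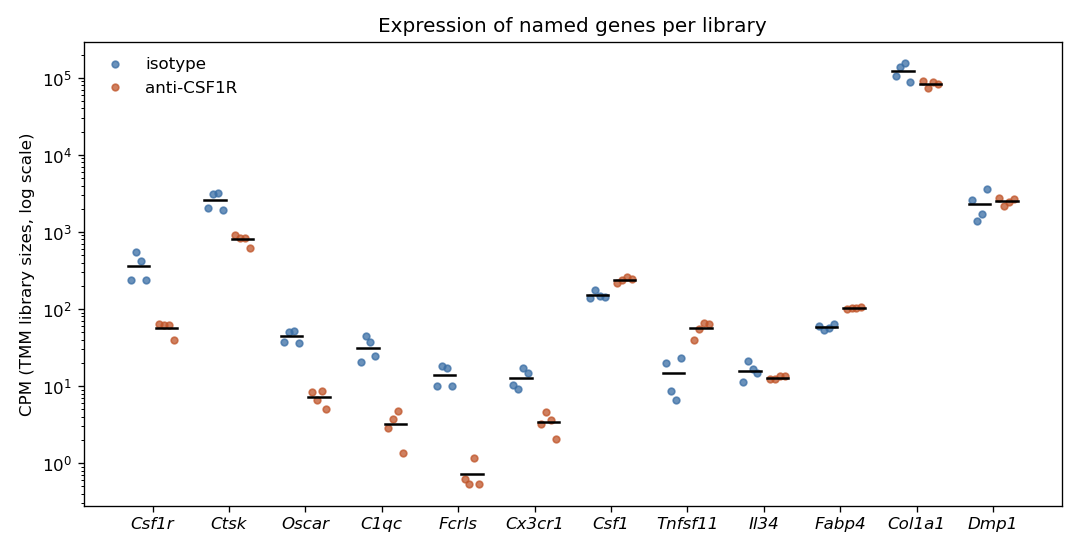
CPM on a log axis of 12 named genes in each library (points), with the group mean (line); blue is isotype and orange anti-CSF1R, n = 4 each. Csf1r, Ctsk, Oscar, C1qc, Fcrls and Cx3cr1 lie lower in every anti-CSF1R library than in any isotype library, while Il34, Col1a1 and Dmp1 overlap or did not pass the test.

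Osteoclast genes fell together. Of 18 measured members of the osteoclast list, 9 fell and 0 rose over all genes, and 16 fell adjusted over the list alone. The median log2 fold change was -1.45 (camera adjusted p = 4.92e-27, and adjusted p = 0.0211 with an estimated correlation). Oscar, an activating receptor of osteoclasts, fell from 44.0 ± 8.45 to 7.17 ± 1.72 CPM, 6.13-fold lower (edgeR adjusted p = 0.00584). Ctsk, the gene of the bone collagen protease cathepsin K, fell from 2584 ± 705 to 797 ± 119 CPM (3.24-fold, edgeR adjusted p = 0.0198). Siglec15, a receptor of fusing osteoclasts, fell 3.09-fold and Nfatc1, the transcription factor that drives their differentiation, 1.88-fold (edgeR adjusted p = 0.0156 and 0.0231). Anti-CSF1R 10 had the lowest osteoclast score, 4.83 against 5.25 to 5.39 in the other anti-CSF1R libraries. Isotype 3 and 4 had the highest scores, 6.85 and 6.67, against 6.50 and 6.48 in isotype 2 and 5. With isotype 2 and 5 only the log2 fold changes of Oscar, Ctsk, Siglec15 and Nfatc1 were -2.36, -1.31, -1.59 and -0.84. On all libraries they were -2.62, -1.70, -1.63 and -0.91. Over all genes, 16 members fell with isotype 2 and 5 only and 15 with the offset.

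Macrophage genes fell as well. The macrophage list had 9 of 19 measured members lower over all genes, 12 lower adjusted over the list alone and a median log2 fold change of -1.55 (camera adjusted p = 5.29e-16, and adjusted p = 0.0211 with an estimated correlation). Csf1r, C1qc, Ms4a7 and Cbr2 had the smallest p-values. The score of the osteoclast list relative to that of the macrophage list was 2.96 ± 0.189 with isotype and 2.86 ± 0.181 with anti-CSF1R, a difference of -0.10 (exact permutation p = 0.514). That difference turned to 0.66 when medians over members replaced means (exact permutation adjusted p = 0.0857) and to 0.03 with isotype 2 and 5 only. These values do not show that the 2 lists fell by the same amount. Microglia markers, some shared with bone macrophages, had 2 of 8 members lower over all genes and 3 adjusted over the list alone (median -0.60, camera adjusted p = 6.11e-06, and adjusted p = 0.0274 with an estimated correlation). Fcrls was among those that fell. P2ry13 stood at 1.11 and 0.276 CPM and Tmem119, a gene that osteoblasts also express, at 385 and 220 CPM, neither past the threshold (edgeR adjusted p = 0.0522 and 0.278). P2ry13 passed with isotype 2 and 5 only and with the offset (edgeR adjusted p = 0.0141 and 0.0138), in a range of 4.31e-05 to 0.182 over 17 alternatives. The log2 fold change of Tmem119 went from -0.81 to -0.11 with isotype 2 and 5 only.

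The acid-secreting machinery was lower as well. Of 15 subunit genes of the vacuolar ATPase, the proton pump of lysosomes and of the osteoclast ruffled border, 1 fell over all genes and 12 adjusted over the list alone. The median log2 fold change was -0.90 (camera adjusted p = 2.89e-10, and adjusted p = 0.0419 with an estimated correlation). Atp6v1b2 fell from 335 ± 133 to 94.1 ± 11.9 CPM (3.57-fold, edgeR adjusted p = 0.0267). Its log2 fold change was -1.83, and -1.27 with isotype 2 and 5 only. Atp6v0c, Atp6v1e1 and Atp6v1d had log2 fold changes of -1.39, -1.43 and -0.68 with edgeR adjusted p-values of 0.0699, 0.0690 and 0.0710. All 3 passed with isotype 2 and 5 only, at -0.79, -0.80 and -0.74 (edgeR adjusted p = 0.00119, 5.62e-04 and 4.66e-04), and with the offset, at -1.11, -1.31 and -1.23 (0.0114, 0.0214 and 0.0298). Over 18 alternatives the adjusted p of these 3 genes ranged from 5.95e-05 to 0.470 with edgeR, DESeq2 or limma. With isotype 2 and 5 only 13 members fell over all genes, and 10 with the offset. The vacuolar ATPase score too was highest in isotype 3 and 4 (7.08 and 6.81, against 6.53 and 6.51). The lysosome list had 0 of 18 members past the threshold over all genes in edgeR and 14 lower adjusted over the list alone (median -0.74, camera adjusted p = 1.02e-07, and adjusted p = 0.636 with an estimated correlation). Its most abundant members, Psap and Ctsb, stood at 1037 and 759 CPM with isotype and 568 and 456 CPM with anti-CSF1R (edgeR adjusted p = 0.223 and 0.213). With isotype 2 and 5 only the list's median was -0.31, and Psap and Ctsb went from -0.87 and -0.73 to -0.32 and -0.31. Ctsb then passed (edgeR adjusted p = 0.0444; range over 18 alternatives 0.0444 to 0.915). With the offset the list's median was -0.57. Isotype 3 and 4 had the highest lysosome scores, 8.30 and 7.99, against 7.48 and 7.49 in isotype 5 and 2 and 7.04 to 7.23 with anti-CSF1R.

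**Figure D3:**
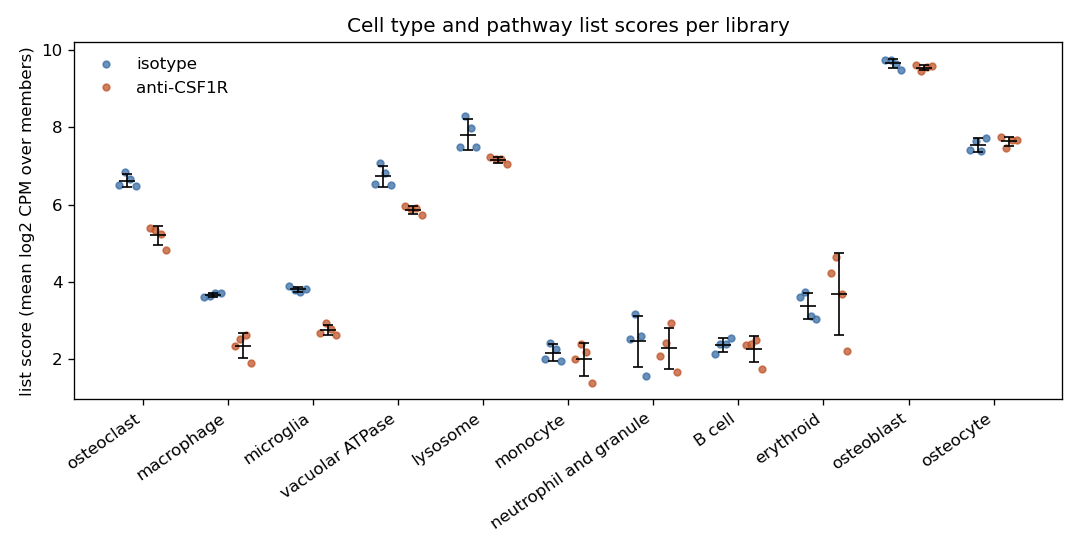
List scores (mean log2 CPM of the members, y axis) for 11 gene lists in each library (points), with group mean and SD (bars), n = 4 each. The osteoclast, macrophage, microglia, vacuolar ATPase and lysosome scores of all 4 anti-CSF1R libraries lie below those of all 4 isotype libraries; the monocyte, neutrophil, B cell, erythroid, osteoblast and osteocyte scores overlap.

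Of the other blood and marrow cell lists, only the T and NK cell list was called on all libraries. The monocyte list had 2 of 13 members lower over all genes, and 3 lower and 1 higher adjusted over the list alone, with a median log2 fold change of 0.01 (camera adjusted p = 0.390). Cx3cr1, the fractalkine receptor, fell from 12.8 ± 3.80 to 3.37 ± 1.05 CPM (edgeR adjusted p = 0.0267). Ccl9, a chemokine also made by osteoclasts, fell from 64.6 ± 30.5 to 14.9 ± 4.99 CPM (log2 fold change -2.12, edgeR adjusted p = 0.0389). Ccl9 lost the call with isotype 2 and 5 only (-1.56, edgeR adjusted p = 0.104) and kept it with the offset (-2.78, edgeR adjusted p = 0.0223). Its adjusted p ranged from 1.10e-06 to 0.279 over 18 alternatives with edgeR, DESeq2 or limma. Clec4a1 and Ms4a4c had log2 fold changes of -0.67 and 1.33 (edgeR adjusted p = 0.248 and 0.131). The monocyte score rose relative to the macrophage score, from -1.51 ± 0.233 to -0.356 ± 0.166, a difference of 1.15 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0429). With medians over members it was 1.37 (exact permutation adjusted p = 0.0857). The monocyte score itself was 2.16 ± 0.220 with isotype and 1.99 ± 0.432 with anti-CSF1R, so the difference restates the fall of the macrophage score. In the dendritic cell and MHC class II list 1 of 14 members fell, over all genes and over the list alone (median -0.21, camera adjusted p = 0.291). Itgax, the gene of CD11c, fell 2.66-fold (edgeR adjusted p = 0.0491). Cd209a, Clec9a and Cd74 had log2 fold changes of -1.62, 1.26 and -0.67 (edgeR adjusted p = 0.224, 0.278 and 0.283). Those of Cd209a, Clec9a and Cd74 went to -0.66, 0.71 and -0.0082 with isotype 2 and 5 only. Clec9a, highest among isotype libraries in isotype 5, passed without that library (2.18, edgeR adjusted p = 0.0402; range over 18 alternatives 0.0402 to 0.915). No member passed over all genes in the neutrophil (20 members, median -0.43, camera adjusted p = 0.666), erythroid (16, 0.36, 0.429), megakaryocyte and platelet (11, 0.40, 0.792), or haematopoietic stem and progenitor list (11, 0.44, 0.292). The same held for the mast cell, basophil and eosinophil (10, -0.61, 0.413) and B cell lists (16, -0.32, 0.413), though 1 B cell gene was lower adjusted over the list alone. The erythroid list was called higher without anti-CSF1R 10, which had its lowest score (median 0.65, camera adjusted p = 1.14e-04), and with the muscle covariate (0.82, 0.0158), in a range of 1.14e-04 to 0.982 over 19 alternatives. The megakaryocyte list was called higher without anti-CSF1R 10 (0.63, camera adjusted p = 0.0197; range over 19 alternatives 0.0197 to 0.984). The most abundant members, S100a9, Hbb-bs, Gp1bb, Cd34, Prg2 and Ighm, had log2 fold changes of 0.26, -0.19, -0.44, -0.27, -1.35 and -0.16. That of Prg2 ranged from -2.01 to -0.79 without each library in turn. The T and NK cell list was called lower (10 members, median -0.40, camera adjusted p = 0.0409, and adjusted p = 0.736 with an estimated correlation). The member that passed, over all genes and over the list alone, was Cd4. Cd2, Nkg7 and Trbc2 had group means of 0.545 CPM or less, with edgeR adjusted p-values of 0.377, 0.354 and 0.305. That list's call was lost without any of isotype 2, 3, 4 or 5 or anti-CSF1R 7 (camera adjusted p = 0.0507, 0.104, 0.0626, 0.0962 and 0.0800) and with isotype 2 and 5 only (0.696), in a range of 0.00713 to 0.736 over 19 alternatives.

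Among the regulators of osteoclasts, Tnfsf11, the gene of RANKL, stood at 14.6 ± 8.15 CPM with isotype and 56.2 ± 11.6 CPM with anti-CSF1R, 3.86-fold higher but not past the threshold over all genes (log2 fold change 1.95 ± 0.40, edgeR adjusted p = 0.0710). It passed with isotype 2 and 5 only (1.38, edgeR adjusted p = 0.0351) and with the offset (1.82, edgeR adjusted p = 0.00843), in a range of 5.47e-05 to 0.615 over 18 alternatives. The list of CSF1R ligands and osteoclast regulators as a whole was not called (12 members, camera adjusted p = 0.792). Ccl9 fell over all genes, and adjusted over the list alone 2 members, Tnfsf11 and Csf1, were higher and 1, Ccl9, lower. Cthrc1 had a log2 fold change of -0.36 (edgeR adjusted p = 0.278).

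Bone-forming cell markers did not pass. The osteoblast list had 0 of 18 members past the threshold in edgeR over all genes and 1 lower adjusted over the list alone (median -0.36, camera adjusted p = 0.292). Col1a1 and Col1a2, the chains of type I collagen, stood at 121490 ± 29920 and 110520 ± 27590 CPM with isotype and 83996 ± 7761 and 79087 ± 6089 CPM with anti-CSF1R (edgeR adjusted p = 0.278 for each). The osteocyte list had 0 of 12 members past the threshold in edgeR by either count (median 0.07, camera adjusted p = 0.902). Dmp1 and Phex, which control bone mineral, had log2 fold changes of 0.10 ± 0.29 and 0.67 ± 0.47 (edgeR adjusted p = 0.811 and 0.344). With isotype 2 and 5 only that of Dmp1 turned to -0.32 and that of Phex went to 0.0067. Phex stood at 299 and 168 CPM in isotype 3 and 4 and at 841 and 898 CPM in isotype 2 and 5. Relative to the osteoclast score, the osteoblast score rose from 3.04 ± 0.153 to 4.35 ± 0.280, a difference of 1.31 (exact permutation p = 0.0286, adjusted p = 0.0429), and 0.60 with medians over members (exact permutation adjusted p = 0.171). The osteoblast score itself was 9.67 ± 0.119 with isotype and 9.55 ± 0.0695 with anti-CSF1R, so the difference restates the fall of the osteoclast score. The fibrillar and basement membrane collagen list had a median of -0.33 (15 members, camera adjusted p = 0.0831), with 0 members past the threshold in edgeR by either count. It was called lower with isotype 2 and 5 only (0.0117) and with the offset (0.0107), in a range of 0.00509 to 0.736 over 19 alternatives. On all libraries it had an adjusted p = 0.736 with an estimated correlation in camera, and 0.0803 with fry. The suture and periosteal mesenchyme (16 members, median 0.01, camera adjusted p = 0.926), Wnt target and antagonist (12, 0.16, 0.577) and matrix protease (14, 0.25, 0.666) lists were not called. Wif1, a secreted Wnt inhibitor, stood at 746 ± 131 and 1228 ± 139 CPM (edgeR adjusted p = 0.117), and was the one Wnt gene higher adjusted over the list alone. It passed with isotype 2 and 5 only and with the offset (edgeR adjusted p = 0.0361 and 0.0406), in a range of 0.00415 to 0.660 over 18 alternatives. Postn and Mmp13 had log2 fold changes of 0.29 and 0.71 (edgeR adjusted p = 0.667 and 0.290), which went to -0.38 and 0.16 with isotype 2 and 5 only.

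Lists of neighbouring tissues differed between single libraries as well as between groups. The skeletal muscle list was called lower (10 members, median -2.07, camera adjusted p = 9.55e-04, and adjusted p = 0.736 with an estimated correlation), with 0 members past the threshold over all genes in edgeR and 6 lower adjusted over the list alone. Its score was 1.40 and 2.86 in isotype 2 and 3 and between -0.69 and -0.03 in the other 6 libraries. Acta1 stood at 10.9 and 22.8 CPM in these libraries and at 0.462 CPM or less elsewhere. Des had a log2 fold change of -0.66 (edgeR adjusted p = 0.286), and -0.04 with isotype 2 and 5 only. The call was lost with the filter of 1 CPM (median -0.66, camera adjusted p = 0.247; range over 19 alternatives 3.44e-07 to 0.736). The cartilage list was called lower (12 members, median -1.50, camera adjusted p = 0.0138, and adjusted p = 0.790 with an estimated correlation), with 0 members past the threshold in edgeR over all genes and 4 lower adjusted over the list alone. With the offset the list was still called lower (median -1.36, camera adjusted p = 0.0347), though the 1 member past the threshold over all genes was higher. The cartilage score was 6.67 in isotype 5, 4.67 to 5.30 in the other isotype libraries and 2.88 to 4.91 with anti-CSF1R, and the call was lost without isotype 5 (median -0.85, camera adjusted p = 0.290; range over 19 alternatives 4.65e-09 to 0.790). Col2a1 stood at 749 ± 812 and 94.9 ± 69.3 CPM and Acan at 161 ± 112 and 55.6 ± 16.6 CPM (edgeR adjusted p = 0.199 and 0.212). The adipocyte list was called higher (5 members, median 0.48, camera adjusted p = 0.0331, and adjusted p = 0.249 with an estimated correlation), with Fabp4 as the member that rose over all genes and over the list alone. Pparg, Lpl and Plin1 had edgeR adjusted p-values of 0.277, 0.301 and 0.529. The list's call was lost with the offset (camera adjusted p = 0.168) and without isotype 2 or 5 or anti-CSF1R 7 or 9 (0.120, 0.156, 0.0682 and 0.0570), in a range of 2.76e-06 to 0.249 over 19 alternatives. It was kept with isotype 2 and 5 only (median 0.73, camera adjusted p = 2.76e-06) and with fry (fry adjusted p = 0.00731).

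The remaining lists were not called on all libraries. The complement and scavenger receptor list had 1 of 16 members lower over all genes and 4 adjusted over the list alone (median -0.19, camera adjusted p = 0.222). The median was 0.06 with isotype 2 and 5 only, with 2 members higher and 3 lower over all genes. Complement C2 fell from 34.7 ± 15.5 to 8.46 ± 1.13 CPM (edgeR adjusted p = 0.0267). C3ar1, Cfb and Stab1 had log2 fold changes of -1.42, -0.77 and -0.66 (edgeR adjusted p = 0.0757, 0.141 and 0.143). C3ar1 passed with isotype 2 and 5 only and with the offset (edgeR adjusted p = 0.0168 and 0.00725; range over 18 alternatives 1.59e-04 to 0.229), and so did Stab1 (0.0458 and 0.0233; range 0.0174 to 0.740). The log2 fold change of C2 was -1.34 with isotype 2 and 5 only. The vascular endothelium list had a median of 0.21 (15 members, camera adjusted p = 0.143). It was called higher with isotype 2 and 5 only (9.73e-07) and with the offset (3.75e-04), in a range of 9.73e-07 to 0.736 over 19 alternatives. On all libraries it had an adjusted p = 0.736 with an estimated correlation in camera, and 0.0787 with fry. Median log2 fold changes and camera adjusted p-values were 0.43 and 0.663 for lymphatic endothelium, -0.18 and 0.953 for pericytes and smooth muscle, 0.12 and 0.895 for dura and arachnoid fibroblasts, 0.36 and 0.429 for skin epithelium, 0.04 and 0.693 for neurons and glia, and -0.34 and 0.663 for Schwann cells. They were 0.02 and 0.739 for proliferation, 0.0022 and 0.926 for interferon response, 0.21 and 0.919 for cytokines and chemokines, -0.07 and 0.725 for immediate early and heat shock genes, and 0.16 and 0.429 for mitochondrially encoded genes. In edgeR 0 members of these 12 lists passed over all genes. Adjusted over the list alone, 2 dura genes and 1 neuronal gene were lower, and 1 cytokine gene was higher and 1 lower. The most abundant members Eng, Pdpn, Pdgfrb, Aebp1, Sbsn, Map2, Egr2, Mki67, Cxcl12, Egr1 and COX1 had log2 fold changes of -0.02, -0.50, 0.26, -0.24, 0.35, 0.77, 0.07, 1.10, 0.44, 0.19 and 0.13. Pdgfrb and Cxcl12 passed with isotype 2 and 5 only, at 0.45 and 0.77 (edgeR adjusted p = 0.0113 and 0.00258; ranges over 18 alternatives 0.0113 to 0.915 and 0.00258 to 0.596). Mki67 went to 0.50, Eng to 0.27, Egr2 to -0.12 and COX1 to -0.43 in that fit. The mitochondrially encoded list, whose share of counts was low in isotype 3 and 4, turned to a median of -0.34 with isotype 2 and 5 only (camera adjusted p = 3.45e-04; range over 19 alternatives 3.45e-04 to 0.959). Median, mean and test differed in sign for the monocyte, CSF1R ligand and regulator, dura, pericyte, neuron, interferon, cytokine, and immediate early and heat shock lists.

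**Figure D4:**
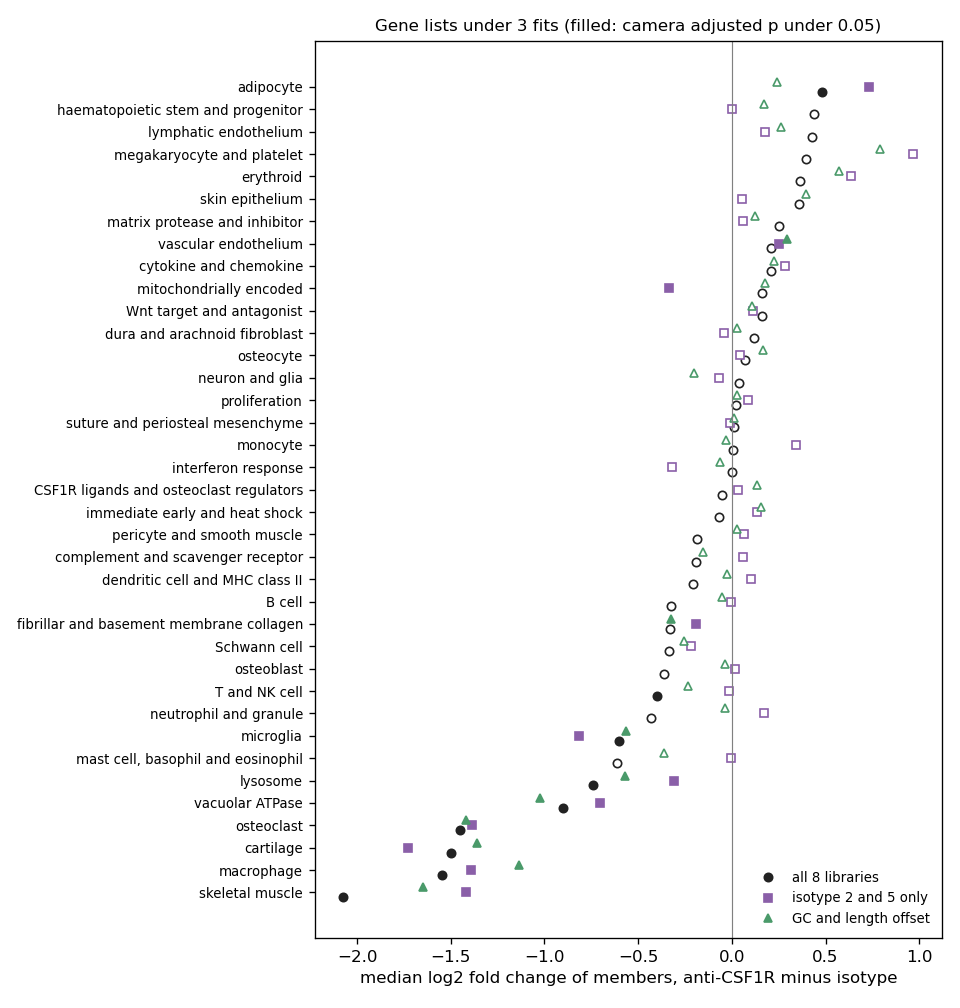
Median log2 fold change of the members (x axis, anti-CSF1R minus isotype) of the 37 gene lists (y axis) with all 8 libraries, with isotype 2 and 5 only and with the GC and length offset; filled symbols have a camera adjusted p under 0.05. The osteoclast, macrophage, microglia, vacuolar ATPase, lysosome, cartilage and skeletal muscle lists lie below 0 and are filled in all 3 fits, with medians from -0.31 to -2.07; of these, the lysosome, cartilage and skeletal muscle lists were not called with an estimated correlation (camera adjusted p = 0.636, 0.790 and 0.736).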

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

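The tests of the isotype pair standing apart, of that pair alone carrying the fall, and of fewer marrow and blood cells were chosen after the result was seen. A sample was marked when its gap to the nearest other library of its group was large against the range of the 4 libraries. Chance marks about 1 in 20 groups, and 11 of 222 groups tested were marked, so single marks carry little weight.

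Of these 11, 6 were the lowest value in anti-CSF1R 10: Csf1r at 39.4 CPM (61.4 to 64.4 in the other 3), Siglec15 at 4.89 CPM (7.49 to 7.88), Atp6v1d at 42.6 CPM (47.4 to 47.9), Ms4a7 at 0.594 CPM (1.33 to 1.43), Qprt at 0.578 CPM (1.21 to 1.29) and Plin1 at 0.231 CPM (0.340 to 0.346). Csf1r and Ms4a7 are on the macrophage list, Siglec15 on the osteoclast list, Atp6v1d on the vacuolar ATPase list and Plin1 on the adipocyte list. Fcrls stood highest in anti-CSF1R 9 at 1.18 CPM (0.528 to 0.623 in the others) and Clec9a, a dendritic cell gene, in isotype 5 at 1.12 CPM (0.229 to 0.264). Among list scores, haematopoietic stem and progenitor genes stood at 3.58 in anti-CSF1R 9 (3.52 to 3.53), dura and arachnoid genes at 3.22 in anti-CSF1R 8 (3.02 to 3.04) and proliferation genes at 4.24 in isotype 4 (4.49 to 4.52). The causes were not tested.

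Osteoclast and macrophage genes fell together, with a median log2 fold change of -1.47 over the 37 members of both lists. The median stayed at -1.29 with the GC and length offset (95% interval -2.08 to -0.79). After the offset the SD of the deviation across genes was still 0.612 and 0.567 in isotype 3 and 4. It was 0.182 to 0.328 in the others, so the offset alone cannot exclude such bias. Without isotype 3 and 4 the median was -1.39 (-1.69 to -0.64), so that pair, with its bias, does not alone carry the fall. The 95% intervals in this paragraph run over list members, which are not independent, and hold no spread between libraries. Fewer marrow and blood cells of every kind would lower the monocyte, neutrophil, erythroid and B cell genes as well. Their median was -0.07 (-0.40 to 0.17, 65 members), 1.41 above that of the 2 lists. By list, in that order, it was 0.01, -0.43, 0.36 and -0.32, so the pooled value joins lists of opposite sign. None of these lists was called on all libraries. Loss of CSF1R-dependent cells could give the fall of the osteoclast and macrophage lists, and so could lower expression per cell. RNA of whole bone does not separate these. Of the 35 ways to split the libraries 4 and 4, the split by treatment was the 1 with as many genes, and edgeR called at most 0 genes in any other split. Every other split mixes the treatments within a group, which adds the treatment difference to the spread. The 0 calls there do not bear on what caused the fall of these 2 lists.

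Isotype libraries 3 and 4 stood apart from the other 6 for a reason that GC content and transcript length carry in large part: these explained at least 0.552 of the variance of their deviation across genes. Lower depth is excluded, as the lower total of the pair, 62337000 counts, lay within the range of the others. An exchange of labels with treated libraries is excluded too, as the lower osteoclast score of the pair lay 1.27 above the highest anti-CSF1R score (SD 0.26 in that group). The labels give no batch and no RNA quality, so the step at which the bias arose was not tested, and no biological explanation was tested.

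Csf1 stood 0.66 higher in log2 with anti-CSF1R, a difference that did not pass on all libraries and passed in 5 of 18 alternatives. Lost myeloid RNA raising the share of every other transcript would give a rise of 0.0228, below the lower end of the 95% interval of 0.33. The genes called lower in any of 3 fits held 3.30% of counts with isotype, so even their full loss could not reach 0.33. Transcripts of lost cells that were not called are left out, and TMM factors are meant to correct for such a shift. This value therefore decides little. The value was 0.85 with the GC and length offset (95% interval from 0.63) and 0.78 with isotype 2 and 5 only. The fit without isotype 3 and 4 argues against GC and length bias of that pair as the cause. The pair still stood out after the offset, so the offset alone cannot exclude such bias. No biological explanation for the difference was tested.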

How the results depend on the processing

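The alternatives with isotype 2 and 5 only, with the GC and length offset and with halved counts were chosen after the data were seen. The number of genes called was the least stable result, and the genes and lists past the threshold kept their direction throughout. The values of the printed genes past the threshold did not overlap between the groups, so leaving out 1 library could hardly turn their direction. The 0 reversed genes below are therefore no measure of stability. For 21 printed genes past the threshold, 180 of 210 values kept the call, 30 lost it and 0 reversed, and without 1 library 76 of 168 kept it, 92 lost it and 0 reversed. For the 9 lists called, 81 of 99 kept the call and 18 lost it, and without 1 library 62 of 72 kept it and 10 lost it. For 53 printed genes not past the threshold, 455 of 521 values stayed there with the same sign, 42 gained a call and 24 reversed, and without 1 library 402 of 424 stayed, 10 gained and 12 reversed. For the 28 lists not called, 280 of 308 stayed, 7 gained and 21 reversed, and without 1 library 200 of 224 stayed, 4 gained and 20 reversed. Genes count as reversed when the log2 fold change turned and lists when the direction of the camera test turned, whatever their median did. Their values follow as log2 fold changes (medians for lists); none of the genes among them passed on all libraries, and the cause was not tested.

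With library size only, 8 genes were higher and 90 lower, and the median log2 fold change of all genes was 0.19, against 0.03 with TMM. Eng turned to 0.16, Hbb-bs to 0.024 and Ighm to 0.0037. DESeq2 called 734 genes, 131 higher and 603 lower, with all of the 144 among them. Acan, Acta1, Cfb, Col2a1, Ms4a4c and Psap gained a call with DESeq2 alone (DESeq2 adjusted p = 0.0136, 0.00662, 0.0137, 0.0356, 0.0268 and 0.0455). With limma-voom 9 genes were higher, Eng turned to 0.017 and the pericyte list to -0.14. With no filter on low counts 0 lists were higher (camera; 1 with the filter, and 1 with fry), the suture list stood at 0.0049 and the dura list at 0.13 with another direction in the test. With the filter of 1 CPM the megakaryocyte list stood at 0.26, the dura list at 0.32 and the interferon list at 0.15, again with the test reversed. With halved counts 8 genes were higher.

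With the muscle score as a covariate edgeR called 0 genes, 0 higher and 0 lower (930 with an unadjusted p under 0.05; DESeq2 called 734 without it), and 3 lists were higher. Csf1r stood at -2.37, no longer past the threshold; the covariate takes 1 of 6 residual degrees of freedom and runs with the groups. COX1 turned to -0.091, Dmp1 to -0.24, Egr2 to -0.018, Eng to 0.24, Hbb-bs to 0.45 and Postn to -0.11; the suture list stood at 0.091, the neutrophil list at 0.26 and the immediate early list at -0.0030.

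With isotype 2 and 5 only edgeR called 536 genes, 119 higher and 417 lower, and 2 lists were higher. COX1 turned to -0.43, Cd34 to 0.0021, Dmp1 to -0.32, Egr2 to -0.12, Eng to 0.27, Hbb-bs to 0.45, Nkg7 to 0.93 and Postn to -0.38. The monocyte list stood at 0.34, the dendritic cell list at 0.10, the neutrophil list at 0.17, the mast cell list at -0.0043, the osteoblast list at 0.018, the immediate early list at 0.13 and the mitochondrially encoded list at -0.34. The medians of the complement, pericyte, and CSF1R ligand and regulator lists also turned, to 0.06, 0.06 and 0.03, and those of the interferon, dura, neuron and suture lists to -0.32, -0.04, -0.07 and -0.0089, while the direction of these 7 tests did not. With the GC and length offset the same held for the monocyte, CSF1R ligand and regulator, pericyte and neuron lists, at -0.03, 0.13, 0.03 and -0.20. Score differences were 0.030 for osteoclast minus macrophage, 1.32 for monocyte minus macrophage and 1.21 for osteoblast minus osteoclast; with 15 assignments the exact permutation test cannot pass.

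With the GC and length offset edgeR called 450 genes, 90 higher and 360 lower. Aebp1 turned to 0.026, Eng to 0.29, Hbb-bs to 0.24, Ighm to 0.14, Il34 to 0.13 and Postn to -0.28. The neutrophil list stood at -0.039, the dura list at 0.026, the interferon list at -0.062, the cytokine list at 0.22 and the immediate early list at 0.16. Of the genes called with these 2 alternatives, 53 were higher and 285 lower in both. Without each library in turn, the offset gave 189 to 2052 genes. Medians over members gave score differences of 0.66, 1.37 and 0.60 in the same order. With an estimated correlation camera called 4 lists lower and 0 higher (fry called 4 lower and 1 higher).

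Without each library in turn, edgeR called 0 to 260 genes, 0 to 41 higher and 0 to 245 lower; 0 genes were left without anti-CSF1R 7 or 8, with 1903 and 1597 at an unadjusted p under 0.05. Csf1r ranged from -2.86 to -2.39. Ranges of genes that reversed were COX1 -0.089 to 0.49, Dmp1 -0.081 to 0.40, Egr2 -0.018 to 0.19, Eng -0.18 to 0.19, Hbb-bs -0.38 to 0.27, Postn -0.0081 to 0.76 and S100a9 -0.042 to 0.55. Between 0 and 3 lists were higher, and without anti-CSF1R 10 these took in the erythroid and megakaryocyte lists. Ranges of lists were neutrophil -0.79 to -0.094, erythroid -0.011 to 0.65, megakaryocyte 0.13 to 0.91, osteocyte -0.034 to 0.20, suture -0.083 to 0.079, pericyte -0.38 to 0.0080, interferon -0.20 to 0.29, cytokine 0.16 to 0.51 and immediate early -0.21 to -0.0040. Depth limits genes near the floor of 0.0434 to 0.0522 CPM; with the spread of these 8 libraries, 0.601% of simulated 1.5-fold changes were recovered, so smaller changes can be missed. DESeq2 gives no value for the list tests. The score differences were tried without each library, with a prior count of 0.5, with medians, with isotype 2 and 5 only and with the offset.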

Other observations

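The genes in this part were chosen after their values were seen. Some members of the macrophage list fell and others did not pass. Adgre1, the gene of the F4/80 antigen, fell from 15.7 ± 2.76 to 3.94 ± 1.21 CPM, Cd68 from 137 ± 57.2 to 31.4 ± 7.47 CPM and Aif1 from 3.64 ± 0.434 to 1.32 ± 0.467 CPM (edgeR adjusted p = 0.0173, 0.0266 and 0.0449). Folr2, a marker of resident macrophages, stood at 8.33 ± 0.941 and 8.00 ± 0.445 CPM, Cd163, a haemoglobin scavenger receptor, at 28.6 ± 13.1 and 41.7 ± 1.83 CPM, and Mertk, a receptor for dying cells, at 66.2 ± 28.6 and 96.4 ± 9.22 CPM (edgeR adjusted p = 0.790, 0.299 and 0.295). Whether other cells of the bone carry these transcripts was not tested. In the osteoclast list Acp5, the gene of tartrate-resistant acid phosphatase, fell from 2407 to 435 CPM, and the fusion genes Dcstamp and Ocstamp fell with log2 fold changes of -1.89 and -2.49 (edgeR adjusted p = 0.0344, 0.0267 and 0.0267). Tnfrsf11a, the gene of the RANKL receptor, fell by 1.43 in log2 (edgeR adjusted p = 0.0336), and Car2, the gene of carbonic anhydrase 2, also found in red cells, stood at 39.3 and 39.7 CPM.

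Some genes were higher with anti-CSF1R both with isotype 2 and 5 only and with the GC and length offset, 53 in all, of which Klhdc7a alone also passed on all libraries. Some of the 53 hardly differed on all libraries, with log2 fold changes of 0.0078 in Tmem255b, 0.016 in Myl9 and 0.080 in Mmp11. The 53 genes took in Csf1 and Tnfsf11, the 2 cytokines that drive osteoclast formation. Vdr, the vitamin D receptor, stood at 678 ± 55.8 and 999 ± 94.1 CPM, with log2 fold changes of 0.47 and 0.66 in these 2 fits (edgeR adjusted p = 0.0366 and 0.0333). Ptx3, a soluble pattern receptor, stood at 24.0 ± 2.22 and 39.3 ± 2.36 CPM (edgeR adjusted p = 0.00164 and 0.00222 in these 2 fits). Thbd, the gene of thrombomodulin on endothelium, stood at 47.0 ± 5.76 and 72.4 ± 7.73 CPM (edgeR adjusted p = 0.0172 and 0.0298 in these 2 fits). The CPM means are over all libraries, where Vdr, Ptx3 and Thbd did not pass (edgeR adjusted p = 0.151, 0.0504 and 0.113). Wif1 was among the 53 genes too, with log2 fold changes of 0.52 and 0.82 in these 2 fits. Both fits share the anti-CSF1R libraries and isotype 2 and 5, so they are not independent. On simulated data, with a simpler GC trend than the real one, 9.50% and 7.32% of their calls were false.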
